A study of Mus musculus with 2 samples.

How the data were processed

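RNA was sequenced from colon epithelial cells of C57BL/6 mice, 1 library from a wild type and 1 from a Pkm2 knockout preparation, both after 2.5% dextran sulfate sodium for 3 days. Per the labels, cells were frozen, RNA was taken up in Trizol and libraries were made with a messenger RNA kit. The labels do not say how many animals entered a library, and strand use, read length and the construction of the knockout allele are not given in the sources used here.

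The values were taken as FPKM as the authors deposited them, with 1 value per Ensembl gene, a symbol and a locus. The files carry no header, so the unit was inferred from the submitters' processing notes and the values. Per the submitters' processing notes, the tools were Bowtie2 2.2.9, TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff 1.3.0 and 2.2.1, and the genome build was mm8. The files' own coordinates did not match that build name. Of 22384 gene IDs, 99.4% were found in GENCODE M21, and 99.96% of these had a locus that overlapped the gene on GRCm38, so coordinates are given on GRCm38. Only values above 0 are listed. A gene without an entry need not be unexpressed, since Txnrd1 and mt-Co1, genes used by nearly every cell, are listed in neither library. For the log2 ratio, a gene listed in 1 library alone was set to 0 in the other. This applied to 1780 genes of the wild type library, none above 2.63 FPKM, and to 1591 genes of the knockout library, none above 13.1 FPKM. Among the genes counted as at least 2-fold apart these were 5 of the 176 higher and 3 of the 236 lower ones, and no measured member of a list was among them.

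FPKM divides by transcript length and by the mapped total, so a few abundant transcripts can move all other values. The FPKM summed to 563086 in the wild type and 533792 in the knockout library, and the listed genes of the mitochondrial genome, which do not include mt-Co1, made up 16.8% and 15.1% of these sums. A further 13.2% and 10.97% came from 7 nuclear entries on chromosome 1 with at least 90% of the 31-base words of their transcript found in mitochondrial transcripts, so that both together made up 30.0% and 26.1%. Depth was estimated from the lowest values, which cluster at the worth of 1 fragment. In genes with 1 transcript longer than 1.5 kb, that step was 0.0530 FPKM times kb in the wild type and 0.0465 in the knockout library, from 375 and 378 genes near the step, which gives about 18900000 and 21500000 fragments. A second estimate, the modal ratio of values in 532 genes with a mean under 0.1 FPKM, was 0.912. The 95% counting intervals of a fold are Clopper-Pearson intervals on fragments implied by this step and the longest annotated transcript of the gene. They are approximate and cover counting error only, neither differences between animals nor those between preparations.

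Values of 34 symbols with more than 1 gene ID were summed, which gave 22350 symbols. The log2 ratio was log2((knockout FPKM + 1)/(wild type FPKM + 1)), a scale that understates the difference of low genes, while a fold given with a gene is the plain ratio of its FPKM values. Genes entered the counts when their mean was at least 1 FPKM, which 12429 did. With 1 library per genotype there was no test and no p-value, and genes were counted by size alone at a threshold of 2-fold. Across these genes the median log2 ratio was 0.06, the SD was 0.47, and Pearson's r of log2(FPKM + 1) between the libraries was 0.963, over genes that are not independent replicates. Genes with near-identical copies are named as uncertain, and so are mitochondrial transcripts, which have nuclear copies.

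Gene lists were described by the median log2 ratio of members with a mean of at least 1 FPKM and by its percentile among 10000 random lists of the same size. These were drawn from 20 bins of equal size of the mean log2(FPKM + 1), leaving out the list's own members. A list with at least 5 measured members was said to stand apart when it lay outside the middle 95% of its random lists. The 51 lists held 1018 genes, 969 of them listed in a file. They covered MHC class I, MHC class II, interferon response, cytokines and chemokines, NF-kB targets, cell death and inflammasome, antimicrobial defence, differentiated colonocyte, water and ion transport, drug metabolism and NRF2 targets. They also covered mitosis, DNA replication, Wnt/beta-catenin targets, intestinal stem cell, fetal-like repair epithelium, Notch pathway and YAP/TEAD targets. The metabolic lists were glycolysis, HIF targets outside glycolysis, nuclear-encoded oxidative phosphorylation, tricarboxylic acid cycle, pentose phosphate pathway, serine and one-carbon metabolism, fatty acid synthesis, fatty acid oxidation and ketogenesis, and cholesterol synthesis. Further lists were enteroendocrine cell, goblet cell, tuft cell, epithelial junctions, unfolded protein response, ATF4 targets and p53 targets. Lists of other cell types were T cell, B and plasma cell, macrophage and dendritic cell, neutrophil, erythrocyte, fibroblast, smooth muscle, endothelium, enteric neuron and glia, pancreatic acinar, squamous, small-intestinal and Paneth cell, and distal colon position. Sample checks were cytosolic ribosomal proteins, mitochondrial genome transcripts, immediate early and heat shock genes, and sex-specific genes. Some genes sit in 2 lists, and some of the other cell types' genes, such as Ctss, are also expressed in epithelium.

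Genes were named by a rule. It took Pkm, and the 15 highest and 15 lowest log2 ratios among genes with a mean of at least 5 FPKM. Symbols of clones, gene models, pseudogenes and short RNAs (Gm and a number, ending in Rik or -ps and a number, starting with LOC, Mir, Snor, Rnu or n-R, or BC, AK, AI or AU and a number) and immunoglobulin and T cell receptor segments were left out of these. For each list it took up to 2 members with the highest and 2 with the lowest ratio and, for other cell types, the 2 most abundant, and any member of a list with 5 or fewer measured members. Genes named outside the rule are said to be chosen after their values were seen. The design, the gene lists, this rule and all alternatives but 2 were fixed before the data were examined.

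The list procedure was tested on simulated data made from the means of the real genes, with 200 lists of 20 genes from 11755 genes and 1000 random lists each. With no shift, 4.5% of lists were called higher and 2.5% lower. With a shift of 0.25 in log2, 44% were called higher, with 0.5 it was 96% and with 1 it was 100%. The simulated ratios were drawn independently for each gene from a normal distribution. They had neither the shape of the real ratios nor list members that move together. These rates therefore hold for such simulated data and are not the error rates of the lists described here. Alternatives covered the pseudocount, the filter on low values, 3 rescalings of the libraries, a further one that kept the wild type sum, genes listed in both libraries alone, the handling of symbols with several IDs, the fold threshold, symbols of gene models, the mean in place of the median and unmatched random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.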

Results

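Messenger RNA was sequenced from colon epithelial cells of a wild type C57BL/6 mouse preparation and of a Pkm2 knockout preparation, with 1 library per genotype. Both had received 2.5% dextran sulfate sodium (DSS), a polymer that injures the colon lining when mice take it up, for 3 days. The values were FPKM (fragments per kilobase of transcript scaled to the number of fragments mapped) for 20793 listed genes in the wild type library and 20604 in the knockout library, 19013 of them in both. The steps between the lowest values corresponded to about 18900000 fragments in the wild type library and 21500000 in the knockout library, so that a transcript of 2 kb at 1 FPKM rested on about 38 and 43 fragments. With 1 library per genotype the differences have no replicate check, and every comparison describes these 2 libraries. Counting intervals given with a fold cover counting error only. Values in brackets after a gene are FPKM in the wild type library first and in the knockout library second. Each list is given by its median log2 ratio of knockout over wild type, with the percentile of that median among 10000 random lists matched on expression.

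The first question was how much Pkm transcript each library held, because this gene encodes the pyruvate kinase that the knockout targets. Pkm (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375 on GRCm38) stood at 281 FPKM in the wild type library and 86.2 FPKM in the knockout library, 3.26-fold lower (95% counting interval 3.15 to 3.37). The gene yields the Pkm1 and Pkm2 isoforms by alternative splicing, and a gene-level value covers both, so it did not check the loss of the Pkm2 isoform by itself. The liver-type and red-cell-type pyruvate kinase gene Pklr, chosen after its values were seen, was close in both libraries, at 28.6 and 28.0 FPKM.

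The comparison of the libraries asked how the transcriptome of DSS-treated colon epithelium differed between the genotypes. Among 12429 genes with a mean of at least 1 FPKM, 176 were at least 2-fold higher in the knockout library and 236 were at least 2-fold lower, while 90.2% lay within 1.5-fold. The genes with the largest positive log2 ratios were Ido1, which encodes a tryptophan-degrading enzyme induced by interferon-gamma, and genes of MHC class II antigen presentation. Ido1 (10.3 FPKM in the wild type and 1037 in the knockout) was 101-fold higher (95% counting interval 90.1 to 113), and Cd74 (32.9 FPKM in the wild type and 1617 in the knockout), the invariant chain of MHC class II, was 49.1-fold higher (95% counting interval 45.9 to 52.6). The genes with the largest negative log2 ratios were led by Mptx1, a pentraxin of the intestinal mucosa, at 1004 FPKM in the wild type and 42.4 in the knockout library, 23.7-fold lower (95% counting interval 21.97 to 25.5). They also held Cyp4b1 (19.8 and 0.875 FPKM), a cytochrome P450, St3gal4 (65.9 and 6.01 FPKM), a sialyltransferase, Ggt1 (21.6 and 1.56 FPKM), a gamma-glutamyltransferase, Cyp2d26 (46.5 and 5.61 FPKM) and Clec2e (56.0 and 7.76 FPKM). Short structural RNAs without a poly(A) tail and AY036118, an entry inside a ribosomal RNA locus, were among the 15 lowest ratios too. These are given with the sample checks. Of the genes at least 2-fold apart, the counting interval of the fold excluded 1 for all 176 higher genes and for 232 of the 233 lower genes that had an interval. Choosing genes by a 2-fold difference at this depth made that outcome likely, so it adds little.

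**Figure D1:**
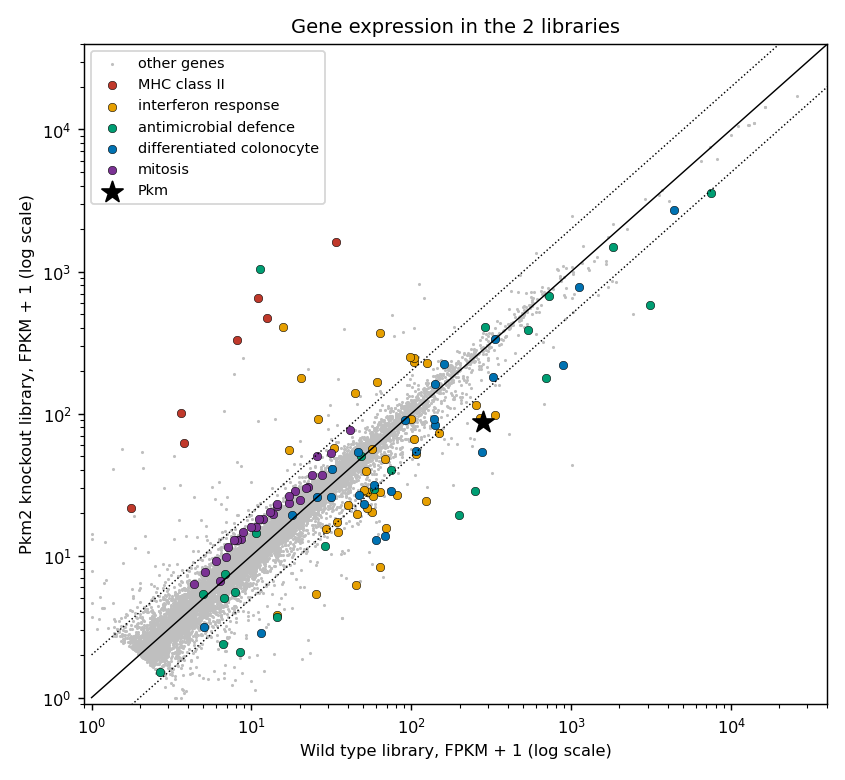
FPKM + 1 in the wild type library (horizontal, log scale) against the Pkm2 knockout library (vertical, log scale) for genes with a mean of at least 1 FPKM, with 5 gene lists coloured, Pkm as a star, equality as a solid line and 2-fold differences as dotted lines. The 7 MHC class II genes lay above the upper dotted line, and Pkm lay below the lower one at 281 and 86.2 FPKM.

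All 7 measured MHC class II genes were at least 2-fold higher in the knockout library, with a median log2 ratio of 5.24, above all 10000 random lists matched on expression. H2-Aa stood at 9.95 and 648 FPKM in the wild type and knockout libraries, H2-Ab1 at 11.4 and 469.5, and H2-Eb1 at 7.09 and 329. The peptide-loading genes were higher too, with H2-DMa (2.78 and 60.6 FPKM) and H2-DMb1 (2.63 and 100.01 FPKM), as was Ciita, the master transcriptional activator of the class II genes, at 0.770 and 20.7 FPKM. Of 14 MHC class I pathway genes, 6 were at least 2-fold higher and 13 had a ratio above 0, among them the immunoproteasome subunit Psmb9 (43.4 and 138 FPKM) and the peptide transporter Tap1 (59.6 and 165 FPKM), and the median was 0.79 (percentile 100). The class I gene H2-Q1 was lower, at 22.8 and 15.4 FPKM.

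Genes of the interferon response list went both ways. Of its 40 genes, 10 were at least 2-fold higher in the knockout library and 18 were at least 2-fold lower, and the median log2 ratio was -0.92 (percentile 0), against a mean of -0.35. The higher genes included Iigp1 (14.8 and 408 FPKM) and Gbp2 (19.3 and 176 FPKM), GTPases that act against intracellular microbes. The lower genes included Ifit3, at 62.3 and 7.24 FPKM, and Rsad2, which encodes the antiviral enzyme viperin, at 43.8 and 5.20 FPKM. Outside the list, the 15 highest ratios also held Gbp4 (2.27 and 49.4 FPKM), a guanylate-binding protein, Ubd (5.78 and 103 FPKM), a ubiquitin-like protein, Wars (37.1 and 390.4 FPKM), a tryptophanyl-tRNA synthetase, and Tgtp1 and Tgtp2, which were 31.3-fold and 27.7-fold higher. Tgtp1 and Tgtp2 are near-identical copies and their separate values are uncertain. Apol10b (1.83 and 28.8 FPKM), an apolipoprotein L gene, was among the 15 too.

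**Figure D2:**
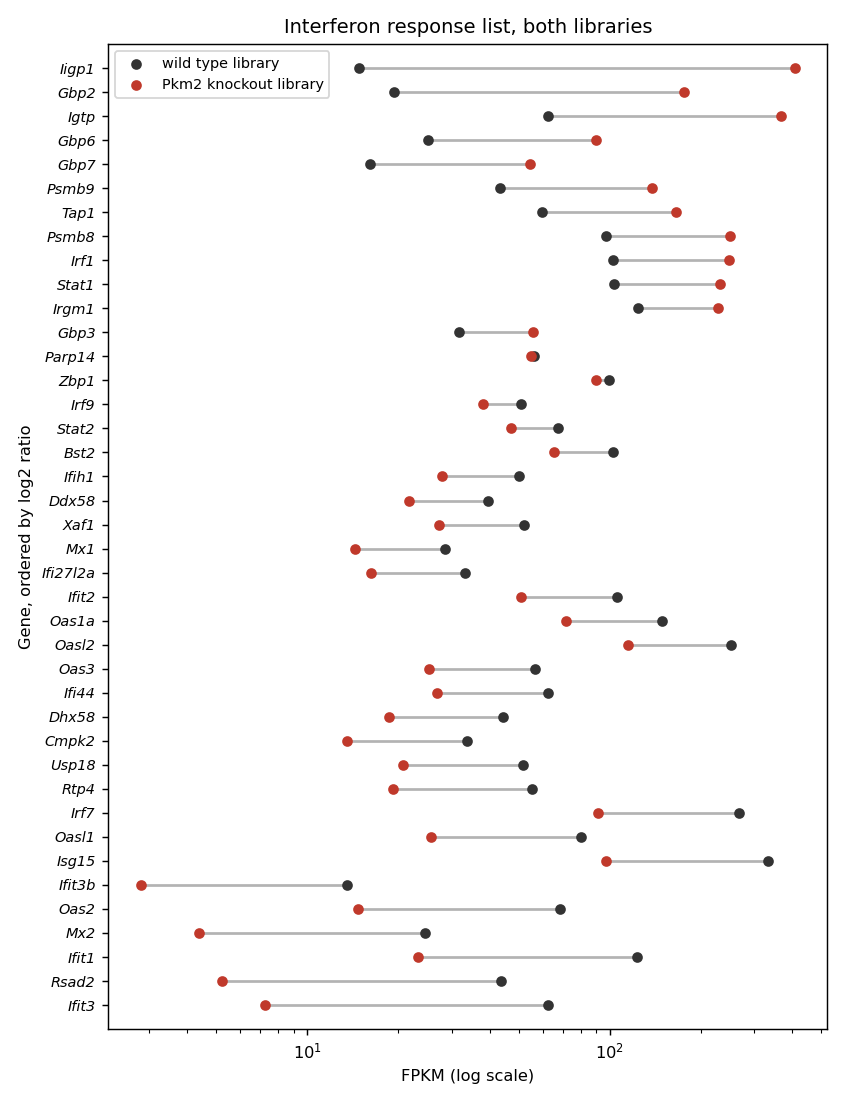
FPKM (horizontal, log scale) of the 40 genes of the interferon response list in the wild type library (dark points) and the Pkm2 knockout library (red points), ordered by log2 ratio. In the knockout library, 12 genes lay to the right, up to Iigp1 at 14.8 and 408 FPKM, and 28 lay to the left, down to Ifit3 at 62.3 and 7.24.

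Cytokine and chemokine genes had a median log2 ratio near 0, 0.01 (percentile 30.8), over 10 measured members, of which 3 were at least 2-fold higher. These included the T cell chemoattractants Cxcl9 (0.854 and 17.9 FPKM) and Cxcl10 (7.16 and 44.3 FPKM), whereas Il18 (34.1 and 20.9 FPKM) was lower. With the mean over members in place of the median, 0.71, or with genes of mean 5 FPKM or more alone, 0.88, the list stood above the random lists. NF-kB target genes did not stand apart, at 0.09 (percentile 56.6), although Icam1 (1.15 and 12.7 FPKM), an adhesion molecule, was 11.1-fold higher. Cell death and inflammasome genes did not either, at 0.09 (percentile 62.4), with Pycard (64.7 and 114 FPKM) higher and Naip1 (39.5 and 24.6 FPKM) lower.

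Antimicrobial defence genes were lower in the knockout library as a group. Of 23 measured members, 9 were at least 2-fold lower and only Ido1 was at least 2-fold higher, with a median of -0.81 (percentile 0). Ang4 (199 FPKM in the wild type and 18.4 in the knockout), an angiogenin with microbicidal activity, was 10.8-fold lower (95% counting interval 9.54 to 12.2). Saa1 (250.2 FPKM in the wild type and 27.5 in the knockout), a serum amyloid A gene, was 9.11-fold lower (95% counting interval 8.63 to 9.63). The resistin-like gene Retnlb (289 and 408 FPKM) was among the few members above 0. The median of the list was -0.47 with a pseudocount of 5 and -0.50 without the filter on low genes.

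Genes of differentiated colonocytes were lower in the knockout library, with a median of -0.70 (percentile 0) over 25 members, 7 of them at least 2-fold lower and none at least 2-fold higher. The carbonic anhydrase gene Car4 stood at 275 FPKM in the wild type and 52.98 in the knockout library, and the water channel gene Aqp8 at 67.3 and 12.7. The list was not uniform, because 7 members had ratios above 0, including the sulfotransferase Sult1a1 (159 and 221 FPKM) and the water channel Aqp4 (30.8 and 39.5 FPKM). The wider list of water and ion transport genes was at -0.20 (percentile 0.02), against a mean of -0.47, with 5 of 25 members at least 2-fold lower, and the chloride channel Cftr (26.2 and 35.4 FPKM) and the bicarbonate transporter Slc4a4 (13.3 and 17.7 FPKM) higher. Drug metabolism genes were lower, at -0.75 (percentile 0), with 11 of 25 at least 2-fold lower, led by the carboxylesterase Ces2a (181 and 30.3 FPKM) and the cytochrome P450 Cyp2d34 (60.6 and 13.3 FPKM). NRF2 targets, genes of the response to oxidants, were at -0.43 (percentile 0.01), with the glutathione transferase Gsta3 (19.4 and 6.90 FPKM) and the ferritin heavy chain Fth1 (1464 and 687 FPKM) at least 2-fold lower.

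Cell cycle genes were higher in the knockout library. All 29 mitosis genes had ratios above 0, with a median of 0.61 (percentile 100) and none at 2-fold, and the largest ratios were those of cyclin A2, Ccna2 (24.7 and 49.3 FPKM), and topoisomerase, Top2a (40.1 and 76.0 FPKM). Of 25 DNA replication genes, 24 had ratios above 0, with a median of 0.32 (percentile 100), among them the flap endonuclease Fen1 (12.7 and 22.2 FPKM) and Cdc45 (6.36 and 10.6 FPKM). Wnt and beta-catenin targets were at 0.43 (percentile 99.99), with Mmp7 (2.55 and 30.4 FPKM), a matrix metalloproteinase, at 11.9-fold and cyclin D1, Ccnd1 (43.2 and 75.4 FPKM), at 1.75-fold, and their median was 0.28 with a pseudocount of 5 and 0.24 without the filter on low genes. Intestinal stem cell genes were at 0.23 (percentile 98.2), with 14 of 16 above 0, including Rgmb (17.0 and 24.4 FPKM) and the transcription factor Ascl2 (4.41 and 6.30 FPKM). Genes of the fetal-like repair epithelium were at 0.25 (percentile 98.7), with Ly6c1 (19.0 and 63.1 FPKM) and Ly6a (476 and 938 FPKM) higher and the growth factor genes Ereg (2.05 and 0.742 FPKM) and Areg (14.0 and 9.01 FPKM) lower. The stem cell list no longer stood apart with the mean over members, and the fetal-like repair list did not under 4 of the alternatives tried. Notch pathway genes, at 0.15 (percentile 82.6), stood above the random lists under 1 rescaling alone, and Notch1 itself was at 5.37 and 10.3 FPKM. YAP and TEAD targets did not stand apart, at -0.07 (percentile 15.6), with Cyr61 (1.41 and 3.01 FPKM) higher and Lats2 (3.07 and 1.61 FPKM) lower.

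Because the knockout targets a glycolytic enzyme, metabolic gene lists were compared next. Glycolysis genes did not stand apart, at -0.04 (percentile 10.97) over 21 members, of which 1, the phosphofructokinase-2 gene Pfkfb4, was at least 2-fold lower at 14.5 and 5.36 FPKM. The phosphoglycerate mutase gene Pgam1 (76.0 and 104 FPKM) had the largest ratio of the list. HIF targets outside glycolysis were slightly lower, at -0.12 (percentile 1.0), with Ankrd37 (11.7 and 2.31 FPKM) and the angiogenic factor Vegfa (36.3 and 18.0 FPKM) lower and the stress-response gene Ddit4 (20.6 and 34.5 FPKM) higher, and their median was -0.19 with equal library medians, -0.18 with equal upper quartiles and their mean -0.30. Of 44 nuclear-encoded oxidative phosphorylation genes, 41 had ratios above 0 and none was at least 2-fold higher, with a median of 0.20 (percentile 99.97) and the largest ratio for Ndufa4 (103 and 163 FPKM), followed by Cyc1 (199 and 272 FPKM). Tricarboxylic acid cycle genes were at 0.20 (percentile 98.8), with 18 of 20 above 0, including Dld (63.2 and 83.1 FPKM) and Idh3a (66.5 and 86.8 FPKM), while the pyruvate carboxylase gene Pcx (8.22 and 5.48 FPKM) was lower. Both of these lists lay within the random range when the mean over members was used, and with equal library medians they were at 0.12 and 0.12.

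Other metabolic lists did not stand apart. Pentose phosphate genes were at 0.17 (percentile 83.6), serine and one-carbon metabolism at 0.25 (percentile 96.9), fatty acid synthesis at 0.22 (percentile 97.2), fatty acid oxidation and ketogenesis at -0.07 (percentile 3.1) and cholesterol synthesis at 0.12 (percentile 75.1). Within them, the serine synthesis genes Phgdh (15.3 and 25.1 FPKM) and Psat1 (5.97 and 12.3 FPKM) and the desaturase genes Scd2 (154 and 228 FPKM) and Fads2 (57.8 and 85.8 FPKM) were higher, and Pdk4 (6.29 and 2.03 FPKM), a kinase that inhibits pyruvate dehydrogenase, was 3.10-fold lower. The serine list stood above the random lists with a pseudocount of 5 and among genes with a mean of at least 5 FPKM, and the fatty acid oxidation list stood below them with the mean over members.

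Secretory lineages of the epithelium were compared as well. Of 13 enteroendocrine genes, 9 had ratios below 0 and none was at least 2-fold lower on the scale with a pseudocount of 1. Their median was -0.56 (percentile 0), and the lowest included the chromogranin gene Chga (83.8 and 44.3 FPKM) and the serotonin synthesis gene Tph1 (23.5 and 11.5 FPKM), whereas the endocrine progenitor factor Neurog3 (0.837 and 1.73 FPKM) was higher. This median was -0.33 with a pseudocount of 5 and -0.24 without the filter on low genes, and their mean -0.36. Goblet cell genes were at -0.07 (percentile 2.9), within the random range, although Reg4 (245 and 65.6 FPKM) and Clca1 (768 and 294 FPKM) were 3.74-fold and 2.61-fold lower, and the list stood below the range with the mean over members. Tuft cell genes were at -0.06 (percentile 20.8), with Dclk1 (5.08 and 4.03 FPKM) as a lower and Ptgs1 (1.21 and 1.91 FPKM) as a higher member. Epithelial junction genes were at 0.09 (percentile 66.7), with E-cadherin, Cdh1 (177 and 232 FPKM), higher and the claudin Cldn4 (14.96 and 8.29 FPKM) lower.

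Of the stress programmes, NRF2 targets stood apart as given above. The others did not, with the unfolded protein response at 0.05 (percentile 41.0), ATF4 targets at 0.11 (percentile 66.1) and p53 targets at 0.02 (percentile 29.0). The endoplasmic reticulum gene Creld2 (28.0 and 36.8 FPKM) was higher and Herpud1 (74.3 and 56.7 FPKM) was lower, and the p53 list held Gtse1 (3.21 and 5.08 FPKM) and Btg2 (31.1 and 22.4 FPKM) at its ends. ATF4 targets stood above the random lists with the mean over members, a list in which Wars had the largest ratio. The combined list of immediate early and heat shock genes, a check of handling stress, stood below the random lists with a median of -0.17 (percentile 0.2) but had a mean of 0.26. Its heat shock members Hspa1a (33.7 and 174 FPKM) and Hspa1b (76.5 and 349 FPKM), near-identical genes whose separate values are uncertain, were higher in the knockout library, and the immediate early genes Ier3 (9.33 and 4.94 FPKM) and Dusp1 (8.17 and 4.997 FPKM) were lower.

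**Figure D3:**
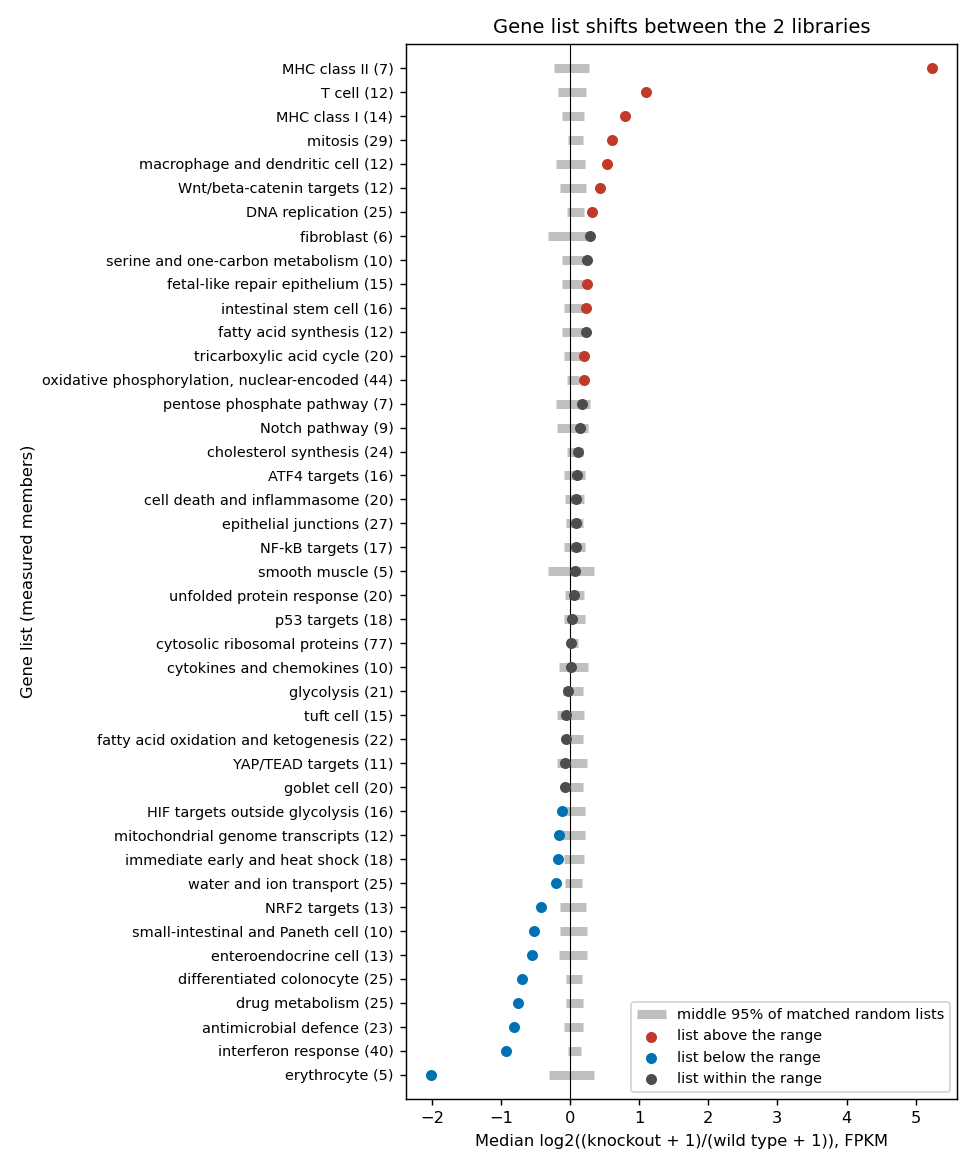
Median log2 ratio of knockout over wild type (horizontal, FPKM with a pseudocount of 1) for the 43 gene lists with at least 5 measured members (vertical, members in brackets), with the middle 95% of 10000 matched random lists as grey bars. Above the bars lay 11 lists, led by MHC class II at 5.24, and below them lay 12, down to erythrocyte genes at -2.01.

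Markers of other cell types differed between the preparations, beside the immune and colonocyte genes above. All 12 T cell genes had ratios above 0 and 8 were at least 2-fold higher in the knockout library, with a median of 1.10 (percentile 100) and the cytotoxic granule genes Gzma (3.34 and 25.0 FPKM) and Gzmb (2.55 and 16.9 FPKM) as the most abundant. This median was 0.61 with a pseudocount of 5. Macrophage and dendritic cell genes were at 0.54 (percentile 99.99), with Fcer1g (0.804 and 4.22 FPKM) and Laptm5 (3.29 and 9.84 FPKM) higher, while the most abundant members Ctss (181 and 125 FPKM) and Cd14 (26.7 and 24.1 FPKM) were lower. The macrophage and dendritic cell median was 0.28 with equal library medians, 0.29 with equal upper quartiles, 0.21 with a pseudocount of 5 and 0.30 without the filter, above the random lists each time. The 4 measured B and plasma cell genes were higher, with Igkc (3.81 and 16.8 FPKM), Igha (3.58 and 12.5 FPKM), Jchain (0.605 and 2.15 FPKM) and Ighm (1.58 and 2.33 FPKM). Of 5 measured erythrocyte genes, the 4 haemoglobin genes were lower, at low levels, with Hbb-bs (8.99 and 0.311 FPKM), Hbb-bt (2.66 and 0.151 FPKM), and Hba-a1 (6.77 and 0.630 FPKM) and Hba-a2 (5.86 and 0.702 FPKM), near-identical genes whose separate values are uncertain. The other member, the bisphosphoglycerate mutase gene Bpgm, was close in both libraries, at 18.6 and 19.6 FPKM. The median of these 5 was -2.01 (percentile 0), -0.93 with a pseudocount of 5 and -3.23 with one of 0.1.

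Small-intestinal and Paneth cell genes were at -0.52 (percentile 0) but went both ways, with Fabp6 (7.64 and 41.6 FPKM) and Mmp7 higher and Rbp2 (7.51 and 0.908 FPKM) and Itln1 (5.68 and 1.37 FPKM) lower, and the list no longer stood apart among genes with a mean of at least 5 FPKM or with the mean over members. Its median was -0.27 with a pseudocount of 5 and -0.31 without the filter on low genes. Of the 3 measured Hox genes that mark the distal colon, Hoxb13 (23.8 and 10.7 FPKM) and Hoxd13 (4.56 and 1.69 FPKM) were lower and Hoxa13 (5.16 and 7.89 FPKM) was higher. Fibroblast genes were at 0.28 (percentile 97.0), with Fbln1 (1.02 and 5.43 FPKM) higher and Dcn (2.65 and 0.870 FPKM) lower, and stood below the random range when low genes were kept. Smooth muscle genes were at 0.07 (percentile 63.2), with Mylk (7.43 and 12.4 FPKM) as the most abundant. Lists with 1 or 2 measured members were the neutrophil list, with Ly6g (25.4 and 13.1 FPKM), the pancreatic acinar list, with Cela1 (47.4 and 31.1 FPKM) and Clps (20.9 and 9.49 FPKM), the enteric neuron and glia list, with Snap25 (2.30 and 1.66 FPKM), and the squamous list, with Sfn (75.1 and 93.9 FPKM). The neutrophil list held 18 genes and the acinar list 13, so these few members do not show whether such cells differed. None of the endothelium genes reached a mean of 1 FPKM.

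Checks of the samples themselves gave further differences. Cytosolic ribosomal protein genes did not stand apart, at 0.02 (percentile 34.6) over 77 genes. Transcripts of the mitochondrial genome were at -0.17 (percentile 2.0), with mt-Nd1 (8116 and 6197 FPKM) and mt-Nd5 (4081 and 3128 FPKM) lower, and were within the random range with the mean over members. The nuclear pseudogenes Gm29216 (25793 and 17096 FPKM) and Gm28661 (16306 and 14515 FPKM) on chromosome 1, chosen after their values were seen, carry nearly the same sequence as mitochondrial transcripts, so that neither their values nor those of the mitochondrial genes are certain. Short structural RNAs without a poly(A) tail were among the 15 lowest ratios, namely Rn7sk (22.3 and 1.06 FPKM), Rn7s1 (35.7 and 2.62 FPKM), Rn7s2 (35.7 and 2.62 FPKM) and Rmrp (11.1 and 0.542 FPKM), where Rn7s1 and Rn7s2 are near-identical copies. The ribosomal RNA entries Rn18s-rs5 (2442 and 500.2 FPKM), mt-Rnr1 (1907 and 845 FPKM) and mt-Rnr2 (1695 and 772 FPKM), chosen after their values were seen, were also lower in the knockout library. Whether the libraries differed in the selection of messenger RNA was not tested. AY036118 (316 and 37.2 FPKM), among the 15 lowest ratios too, lies at 39847113 to 39848035 on chromosome 17, inside the locus of Rn18s-rs5 (39846353 to 39848827) and on the same strand, so its value is uncertain. The Y-linked genes Ddx3y (22.1 and 20.5 FPKM), Uty (10.3 and 8.91 FPKM), Kdm5d (19.9 and 15.6 FPKM) and Eif2s3y (42.7 and 36.4 FPKM) were present in both libraries and Xist, chosen after its values were seen, was at 0.0277 and 0.00928 FPKM.

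Of the 43 lists with at least 5 measured members, 11 stood above and 12 below the middle 95% of their random lists, where about 2.15 would do so by chance if lists were random draws. Genes of a list are not independent of one another, so that number is a guide to these 2 libraries and not a test of genotype.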

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

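The alternatives that kept the wild type sum or took genes listed in both libraries alone were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. The counts of 176 higher and 236 lower genes followed the settings that weigh low genes. With a pseudocount of 0.1 they were 272 and 361, with 5 they were 85 and 124, and among genes with a mean of at least 5 FPKM they were 111 and 154. At 1.5-fold they were 554 and 658, and at 4-fold 51 and 51. A rescaled sum gave 342 and 452. It set the libraries to an equal total over all genes but the 50 highest and those of the mitochondrial genome. Values were then 2.96 and 2.88 times the FPKM, so that the pseudocount and filter weighed less. The same rescaling with the wild type sum kept gave 160 and 257, and genes listed in both libraries alone gave 171 and 233. The 3 rescalings moved the median log2 ratio of all genes by less than 0.1.

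The log2 ratio of Pkm, -1.69, was -1.77 with equal medians, -1.76 with equal upper quartiles and -1.74 with the rescaled sum. Of the lists standing apart, 7 of 11 higher and 9 of 12 lower lists kept their call under every alternative that could be run, and so did 13 of 20 lists that did not stand apart. Several alternatives could hardly change a call, and changed none of the 43. Equal medians, equal upper quartiles and the kept wild type sum move a list and its random lists nearly alike. Genes listed in both libraries alone left out no measured list member, and the handling of several IDs touched few symbols. With the mean over members, these lists no longer stood apart: fetal-like repair epithelium (0.20), intestinal stem cell (0.18), mitochondrial genome transcripts (-0.19), nuclear-encoded oxidative phosphorylation (0.21), small-intestinal and Paneth cell (-0.15), tricarboxylic acid cycle (0.18), and immediate early and heat shock genes, whose sign turned (0.26). With the mean, ATF4 targets (0.34) and cytokines and chemokines (0.71) stood above, and fatty acid oxidation (-0.20) and goblet cell genes (-0.27) below the random lists. Fetal-like repair also lost its call with a pseudocount of 5 (0.17), without the filter (0.15) and with the rescaled sum (0.0807), and small-intestinal genes among genes with a mean of at least 5 (-0.15). Notch genes with the rescaled sum (0.25), cytokines with a mean of at least 5 (0.88), serine genes with a pseudocount of 5 (0.20) or a mean of at least 5 (0.34) and fibroblast genes with a pseudocount of 5 (0.18) stood above. Fibroblast genes stood below without the filter (-0.14). The cause was not tested for these lists. Of 206 named genes other than Pkm, 69 were at least 2-fold apart and kept their sign under the tested pseudocounts and rescalings, and 6 genes near a ratio of 1 did not. For the 69 genes that outcome was fixed in advance, because a pseudocount alone cannot turn the sign of a ratio. The rescalings multiplied the knockout values by 0.946 to 0.971 relative to the wild type, too little to turn a 2-fold difference. Depth limits the low genes most.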

Other observations

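The tests on antigen-presenting cells, cell type lists and Hox genes were chosen after the results were seen, and so was the restriction of the further interferon genes to other gene names. The test on cell type lists replaced tests on the spread (its bound altered once its value was known) and on the signs of colonocyte genes, and the fold of the markers replaced their gain. The test on the strain segment was set before the values it measures were looked at.

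Further interferon-responsive genes were taken from lists drawn up after the fixed list had been seen, but without sight of their own values. Of 15 measured interferon-gamma responsive genes, 13 had ratios above 0, 8 were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 1.15. Among them, the guanylate-binding protein genes Gbp8 (4.67 FPKM in the wild type and 29.2 in the knockout library), Gbp10 (4.90 and 23.9) and Gbp5 (1.26 and 9.56) were higher, as were the transcription factor genes Irf8 (42.2 and 135) and Batf2 (28.9 and 97.0). Cd274 (8.07 and 8.18) and Jak2 (17.7 and 15.6) were close in both libraries, and Socs3, which encodes a suppressor of cytokine signalling, was lower, at 24.3 and 7.63 FPKM. Of 20 type I interferon responsive genes, 16 had ratios below 0 and 3 were at least 2-fold lower, with a median of -0.62. Those 3 were the RNA-sensing genes Oas1b (17.0 and 3.27) and Oas1g (109 and 43.3) and the helicase gene Ddx60 (61.3 and 16.4). Slfn9 (23.9 and 26.4), Phf11b (20.4 and 21.1), Nt5c3 (48.0 and 49.5) and Slfn8 (1.23 and 1.24) were close in both libraries or slightly higher. Ifng itself was not listed in the wild type library and stood at 0.667 FPKM in the knockout library. These members were named after their values were seen.

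The higher MHC class II genes and the lower Ifit, Oas and Mx genes were weighed first. Families within the interferon list were grouped after their values were seen. All 11 Ifit, Oas and Mx genes of that list had ratios below 0. All 7 of its guanylate-binding protein and immunity-related GTPase genes had ratios above 0. Markers of B, plasma, macrophage and dendritic cells moved with the class II genes in part. Of 16 measured ones, 12 had ratios above 0 and 11 a counting interval of the fold above 1. All 4 of the B and plasma cell list, immunoglobulin genes and Jchain, were among the 12. Whether antigen-presenting cells expressed them was not tested. Of 12 macrophage and dendritic cell markers, 8 had ratios above 0 and 4, among them Ctss and Cd14, below. More of the same cells would raise Cd74 no further than markers that those cells alone express. The highest marker, Fcer1g, was 5.25-fold higher (95% counting interval 2.77 to 11.9) against 49.1-fold for Cd74. This argues against such cells as the only source if the markers came from them alone, which was not tested. A cell type without a marker on these lists stays open as well. Without genes whose symbols share their first 3 characters with a gene of the fixed interferon and MHC lists, the 5 further interferon-gamma responsive genes went both ways with a median log2 ratio of 0.0171, so a stronger interferon-gamma response stays open, and the higher median of all 15 rested on genes named like those already seen. The 14 further type I responsive genes left by that rule had a median of -0.51, below all 10000 random lists, with 10 below 0 and none at 2-fold, so a weaker type I response is a candidate explanation for the lower genes. Whether these genes respond to type I interferon alone was not tested. Whether genotype, a difference between animals or preparations, or the T cells whose markers were higher lay behind either part stays open. With 1 library per genotype these cannot be told apart.

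With a smaller share of all colonocytes as the only difference, markers of the other cell types would be higher alike. The T cell median lay 1.66 above the enteroendocrine median in log2 (95% interval 0.88 to 2.24 over resampled members). The gap was at least 0.94 under the 11 alternatives that measured both. Of the T cell, macrophage and dendritic cell, tuft, goblet and enteroendocrine lists, these stood highest and lowest. The interval does not cover that choice, so the gap decides nothing by itself. The enteroendocrine median, -0.56, stood below its random lists under every alternative that could be run, where a smaller colonocyte share alone would raise it. It was the lowest of these lists, and the goblet (-0.07) and tuft (-0.06) medians lay within their random ranges. The lower enteroendocrine genes argue against such a share as the only cause, while a smaller share beside other differences stays open. Neither the SD of the 25 colonocyte ratios, 0.87, nor the 7 members above 0 decided anything, because expression of members in other cells was not tested. A different stretch of colon in the 2 preparations would move the distal Hox genes together, and their median log2 ratio was -1.05 with 2 of 3 lower and Hoxa13 higher, so the stretch and the genotype cannot be told apart with 3 genes that disagree. The genotype and a smaller share of some colonocytes were not tested and stay open.

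A segment of another strain carried along with the Pkm2 allele could also set genes apart. Within 20 Mb of Pkm, 13 of 264 measured genes were at least 2-fold apart, 4.92%, where windows around 1000 other genes had a median of 3.03% and a 95th percentile of 6.92%. The share lay above the median and below the 95th percentile, so such a segment cannot be told apart from the genotype by this count. The 13 genes, seen only after the count, included the neighbouring pair Nxpe4 (9.54 and 0.124 FPKM) and Nxpe2 (30.7 and 9.33), and the T cell receptor complex genes Cd3e (2.05 and 7.52) and Cd3g (3.14 and 7.29).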
